A study of Homo sapiens with 8 samples.

How the data were processed

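Total RNA from 8 human placenta samples was extracted with TRIzol and made into standard Illumina libraries, per the labels' protocols. The labels put 5 samples in the Normal group and 3 in the PTB (preterm birth) group. The submitters' processing notes name CASAVA, HISAT and HTSeq 0.6.0 and the genome build GRCh38. Their parameters, the annotation release, the strandedness of the libraries and the read length are not given in the sources used here.

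The authors deposited RPKM values (reads per kilobase of exon, scaled to the total) in 1 table of 44271 gene rows with exon coordinates and summed exon lengths. RPKM times gene length was a whole multiple of 1 step per library for 100% of the values, within a tolerance of 0.01 reads. Those recovered reads summed to between 42408233 and 44562886 per library, and the sum equalled the denominator of the RPKM values, so RPKM is relative to reads assigned to the listed genes. A change in abundant transcripts, such as the mitochondrial ones, therefore moves the RPKM of all other genes. Depth was similar in the 2 groups, and genes with few reads have the largest counting error.

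The 18232 protein-coding genes whose names matched GENCODE release 29 (GRCh38) overlapped its coordinates in 99.84% of cases and shared an end in 97.94%, so coordinates are those of the deposited table on GRCh38. A spreadsheet-like conversion had turned 28 gene names into dates, and 26 were restored from their coordinates. The gene type of 14430 rows, many with clone-based names, found no match. All 749 symbols of the gene lists were found in the table, by name or an older symbol. Y-linked genes, XIST and TSIX (163 rows) were removed before any test.

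Genes with RPKM of at least 0.5 in at least 3 samples (17181) were tested on log2(RPKM + 1). The tests were 2-sided, with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes with a mean-variance trend, no covariates) and Benjamini-Hochberg adjustment, at an adjusted p below 0.05. Count models were not used as the main test, since the values are not raw counts. As an alternative added after seeing the data, limma voom was run on the recovered reads. The 36 gene lists were tested with limma camera at a preset correlation of 0.01, adjusted over the lists, with the estimated correlation and fry as alternatives. A list score is the mean over measured members of log2(RPKM + 1) minus the gene's mean over all samples. Score differences and the first principal component were tested by exact permutation over all 56 splits of 8 samples into 5 and 3. Lists needed at least 5 measured members.

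The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, by size of change, up to 12 genes per direction past the test with a mean RPKM of at least 1 in at least 1 group and no overlap between groups. Where fewer than 5 pass in a direction, it takes the 12 with the lowest p, named as not passing, here among genes with an annotated type that met the same limits on level and overlap. It adds up to 4 passing members of each list described or, where none passes, the 2 with the largest change, and 22 genes that are always named. Genes on X with a copy on Y were not named. The list of hepatocyte transcripts and the list of PRAME family genes were made after seeing the data.

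Alternatives were a pseudocount of 0.1, no filter on low values, a mean RPKM of at least 2, median-of-ratios scaling, quantile normalisation, a total without globin and mitochondrial reads, robust empirical Bayes, array weights (statmod 1.5.0), the replicate number as a block, and each of the 8 libraries left out in turn. Count-model alternatives planned for a table of raw counts were not run. Alternatives added after seeing the data were voom, the syncytiotrophoblast score as a covariate, and the fit without Normal 2 and Normal 4.

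The tests were checked on simulated reads for 17181 genes with the means, dispersions and depths of these libraries, of which 200 were changed. The test recovered 36 of 100 genes changed 4-fold and 5 of 100 genes changed 2-fold, and called 3 unchanged genes. With no change simulated it called 0 genes. With a dispersion of 0.05 for every gene it recovered 98 of 100 genes changed 4-fold and 49 of 100 changed 2-fold, and called 14 unchanged genes. Each gene was drawn independently, so the simulated reads lacked the correlation between genes of the real libraries. The numbers of unchanged genes called therefore do not give the error in these libraries. No libraries were duplicates, since the closest pair differed by a chi-square of 40.1 per gene.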

Results

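RNA sequencing of human placenta covered 8 samples, of which 5 were labelled Normal and 3 were labelled preterm birth (PTB). Each sample held between 42408233 and 44562886 reads assigned to genes, so 1 RPKM (reads per kilobase of exon, scaled to the assigned total) stood for 42.4 to 44.6 reads per kilobase. Sampling site, gestational length, mode of delivery and batch are not given in the sources used here. Preterm birth is defined by a short gestation, so an effect of gestational length cannot be told apart from that of preterm birth. The same holds for any of the others that differs between the groups. The labels do not say that the samples come from separate placentas, so p-values measure only the spread between these samples, which may be partly technical. Unless stated otherwise, values are RPKM as mean ± SD over n = 3 PTB and n = 5 Normal samples, and log2 differences are PTB minus Normal on the log2(RPKM + 1) scale, which understates the change of genes with low values.

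IGF2, the imprinted fetal growth factor gene, took 13.6% ± 2.0 of the assigned reads in PTB and 13.1% ± 3.4 in Normal samples. Mitochondrially encoded transcripts took 27.4% ± 7.2 in PTB and 20.6% ± 11.3 in Normal samples, with a range of 9.07% to 39.07% within the Normal group. Globin transcripts stayed at or below 0.15% of the reads in every library.

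Libraries differed widely in syncytiotrophoblast transcripts, the products of the multinucleate layer that covers the villi and makes placental hormones. CSH1, which encodes placental lactogen, stood at 12287 RPKM in Normal 4 and 8066 RPKM in Normal 2, and between 243 and 743 RPKM in the other Normal libraries. The PTB libraries held between 122 and 540 RPKM. The first principal component of all tested genes carried 53.1% of the variance, and 35 of the 100 genes with the largest loadings belonged to the 3 syncytiotrophoblast lists, which have 56 tested members. PTB samples had a mean of -25.1 ± 11.8 on this component and Normal samples 15.1 ± 46.7. The difference of -40.2 did not exceed the spread between samples (exact 2-sided permutation p = 0.2321 over 56 splits). Normal 1, Normal 5 and Normal 3 had scores of 0.649, -3.58 and -41.8, against 39.1 and 81.0 in Normal 2 and Normal 4.

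**Figure D1:**
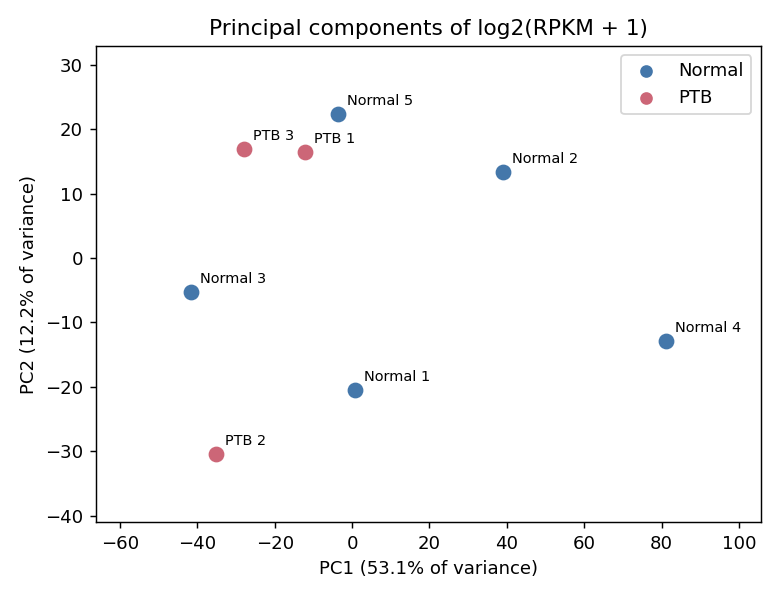
Each point is 1 library (blue, 5 Normal; red, 3 PTB), placed by its scores on the first and second principal components of gene-centred log2(RPKM + 1), with the share of variance on each axis. Normal 4 (81.0) and Normal 2 (39.1) sit apart on the first component, while the PTB libraries lie between -35.2 and -12.2.

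The comparison of PTB with Normal placenta asks which transcripts differ between preterm birth and normal pregnancy. PRAME, a cancer-testis antigen gene, was about 1 RPKM in all PTB libraries and close to 0 in all Normal libraries. GZMB and CD2, genes of cytotoxic lymphocytes and of T and NK cells, had higher means in PTB, while the lowest PTB library and Normal 1 were nearly tied, at 1.646 and 1.639 RPKM of GZMB and 0.815 and 0.789 RPKM of CD2. LGALS13, which encodes the placental galectin PP13, and CGA, which encodes the alpha subunit of chorionic gonadotropin, were below every Normal library in every PTB library. None of these differences passed the correction for 17181 tested genes. In the limma test, 0 genes rose and 0 genes fell in PTB at an adjusted p below 0.05, and 603 genes had an unadjusted p below 0.05, of which 344 were higher and 259 lower in PTB. Chance alone gives 859 such genes. The voom version of the test on recovered reads also called 0 genes, with 585 at an unadjusted p below 0.05. PTB and Normal libraries did not overlap for 419 genes, or 2.44% of those tested, against 3.57% expected by chance. The median standard error of a log2 difference was 0.21.

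PRAME (chromosome 22, 22547701 to 22559361 on GRCh38) had the lowest p of all tested genes. Its mean was 1.01 ± 0.15 RPKM in PTB and 0.037 ± 0.045 RPKM in Normal samples, from 136 to 182 reads per PTB library and 0 to 18 reads per Normal library. The log2 difference was 0.95 with a standard error of 0.10, in 3 of 3 PTB samples, with a limma adjusted p of 0.0847. It was 3.07 with a pseudocount of 0.1 (adjusted p = 0.895) and 5.84 with voom (adjusted p = 0.802). The adjusted p was 0.0382 with median-of-ratios scaling, 0.0337 with quantile normalisation, 0.0413 with the total without globin and mitochondrial reads and 0.0236 with array weights, and over all alternatives in which PRAME was tested it ranged from 0.0236 to 1.00.

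The other genes higher in PTB were taken by lowest p among genes with an annotated type, no overlap between groups and a mean of at least 1 RPKM in a group, and each had a limma adjusted p of 0.880. GZMB was 2.82 ± 1.27 RPKM in PTB and 0.623 ± 0.577 in Normal samples, and CD2 was 1.17 ± 0.44 against 0.234 ± 0.318. RGS1, a regulator of G protein signalling in lymphocytes, was 4.21 ± 1.18 against 1.58 ± 0.72. CP, which encodes the copper-carrying ferroxidase ceruloplasmin, was 1.63 ± 0.36 against 0.519 ± 0.230, and the interstitial collagenase gene MMP1 was 4.51 ± 1.65 against 1.75 ± 0.70. The snoRNA host gene SNHG19 was 1.14 ± 0.16 against 0.229 ± 0.251, CMTM7 was 1.297 ± 0.273 against 0.629 ± 0.103, and ATHL1 was 2.57 ± 0.93 against 1.03 ± 0.37. SNHG19 rested on 14 to 18 reads per PTB library and 0 to 9 per Normal library. GAS6-AS1 was 2.05 ± 0.17 against 1.05 ± 0.29, but it is an antisense transcript, and whether counting used strand is not given in the sources used here. The microRNA precursors MIR6757 (69 bases) and MIR4646 (63 bases) rested on 0 to 15 reads per library, which can belong to longer overlapping transcripts.

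Genes lower in PTB were taken by the same rule, all with a limma adjusted p of 0.880. LGALS13 (chromosome 19, 39602501 to 39607476) had the lowest p among them, at 0.605 ± 0.516 RPKM in PTB and 4.49 ± 2.63 in Normal samples, a log2 difference of -1.68 with a standard error of 0.39. The autophagy gene ATG9B was 3.64 ± 0.95 against 7.08 ± 1.15, and COASY, which encodes coenzyme A synthase, was 9.91 ± 1.52 against 17.2 ± 3.3. SRF, a transcription factor that drives immediate early genes, was 3.93 ± 0.74 against 7.60 ± 2.19, and SERTAD3 was 1.54 ± 0.17 against 2.94 ± 0.62. SPIRE2, an actin nucleator gene, was 0.993 ± 0.411 against 3.00 ± 1.55, and PSCA was 0.169 ± 0.145 against 1.08 ± 0.71. MSMP was 1.44 ± 0.42 against 2.87 ± 0.67, FXYD3 was 0.526 ± 0.133 against 1.13 ± 0.28, and the histone gene HIST1H2AM was 0.398 ± 0.303 against 1.60 ± 1.05. HIST1H2AM rested on 2 to 12 reads per PTB library and 16 to 59 per Normal library. USP46-AS1 was 1.09 ± 0.27 against 2.04 ± 0.44, and the microRNA precursor MIR6126 was 2.90 ± 1.23 against 5.12 ± 0.60, with the same limits on strand and on short transcripts.

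**Figure D2:**
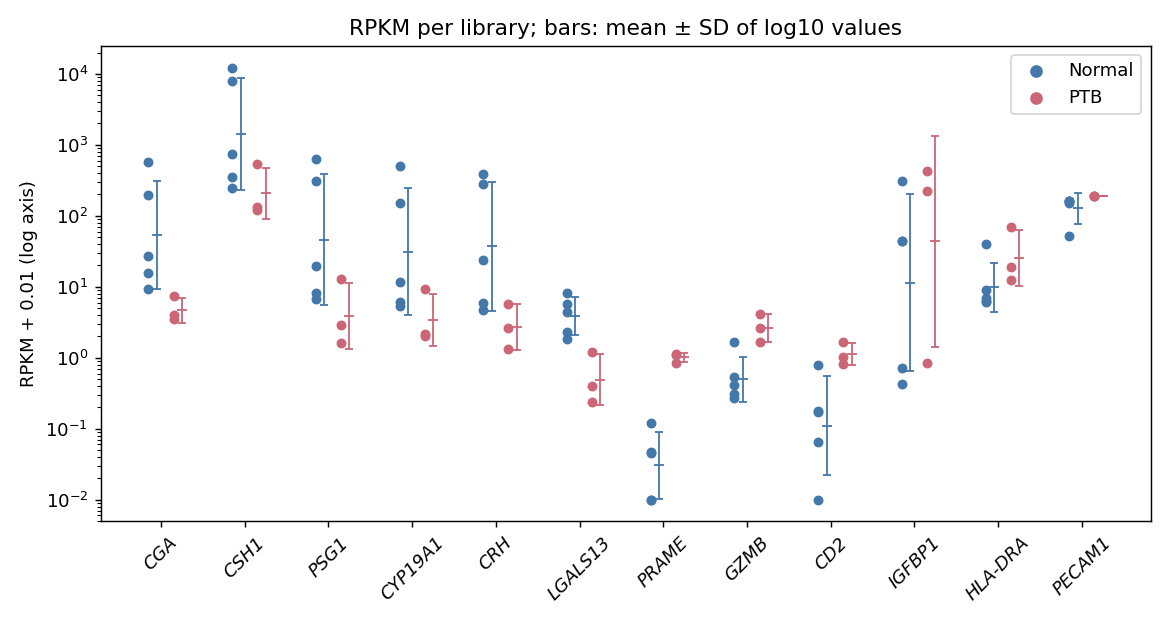
Points are RPKM per library plus 0.01, on a log axis, for 12 genes (blue, 5 Normal; red, 3 PTB), and bars give the mean ± SD of the log10 values. CGA, LGALS13, PRAME and PECAM1 show no overlap between groups, GZMB and CD2 nearly touch at Normal 1, while CSH1 spans 243 to 12287 RPKM within the Normal group.

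Transcripts of the syncytiotrophoblast were lower in PTB in 3 lists, each called by camera in limma with its preset correlation. The camera adjusted p was 8.61e-12 for hormones and secreted proteins, 6.90e-10 for fusion and structure and 6.86e-07 for pregnancy-specific glycoproteins, each with an adjusted p = 0.813 with an estimated correlation. The estimated correlations were 0.79, 0.74 and 0.99, against the preset 0.01. The list scores differed by -1.77, -1.34 and -2.59 between groups, with exact permutation p = 0.1786, 0.1071 and 0.1607. All 27 measured members of the list of placental hormones and secreted proteins had a lower mean on the log2 scale in PTB, as did all 10 pregnancy-specific glycoprotein genes and all 19 genes of syncytiotrophoblast fusion and structure. CGA was 4.92 ± 2.10 RPKM in PTB and 165 ± 243 in Normal samples, CSH1 was 265 ± 238 against 4337 ± 5539, and CRH, which encodes corticotropin-releasing hormone, was 3.21 ± 2.25 against 140 ± 181. PSG1 was 5.75 ± 6.11 against 196 ± 279 and PSG4 was 5.99 ± 6.39 against 265 ± 416, in a gene family whose near-identical copies can share reads. CYP19A1, the aromatase gene of oestrogen synthesis, was 4.44 ± 4.09 against 135 ± 213, and TREML2 was 2.27 ± 2.34 against 64.9 ± 88.6. KISS1 was 21.3 ± 27.5 against 168 ± 200, LEP was 0.333 ± 0.338 against 12.8 ± 24.2, PAPPA2 was 8.33 ± 2.65 against 75.1 ± 125.4, and HSD11B2, which inactivates cortisol, was 3.94 ± 3.45 against 17.4 ± 14.6. Normal 4 and Normal 2, the libraries with the highest CSH1, also had the lowest mitochondrial shares of all, 9.07% and 15.26%. In the Normal group the SD exceeded the mean for each of these genes except HSD11B2. Over all genes, 0 of the members passed, while 1, LGALS13, passed when adjusted over the list alone.

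Leaving out Normal 2 and Normal 4, an alternative chosen after seeing the data, the mean log2 differences of the 3 lists were -0.61, -0.51 and -0.88, against -1.77, -1.34 and -2.59 with all libraries. The 3 calls were kept in that fit with the preset correlation (camera adjusted p = 2.28e-12, 1.65e-11 and 1.34e-09). With the syncytiotrophoblast score as a covariate, which removes most of the difference by construction and was also chosen after seeing the data, the hormone and glycoprotein calls were lost (camera adjusted p = 0.215 and 0.578), as were those of the cytotrophoblast, endothelial, fibroblast, interferon and nutrient transporter lists (0.372, 0.647, 0.578, 0.625 and 0.294). In that fit the fusion and structure call was kept (camera adjusted p = 0.0356), with a mean log2 difference of -0.057. The mitochondrial and ribosomal lists were called lower, not higher (camera adjusted p = 0.00378 and 0.0327), and the histone list turned direction without a call (0.0693).

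The cytotrophoblast and amnion lists also had lower mean scores in PTB (exact permutation p = 0.3036 and 0.2679), while the extravillous trophoblast list was not called. With an estimated correlation the cytotrophoblast and amnion calls were lost (adjusted p = 0.813 for each). Of the 19 cytotrophoblast markers, 17 had a lower mean, including EGFR at 6.67 ± 1.56 against 25.6 ± 27.5 RPKM and the protease inhibitor gene SPINT1 at 10.6 ± 3.2 against 28.5 ± 19.5. This list was called lower (camera adjusted p = 0.00647, and adjusted p = 0.813 with an estimated correlation), with 0 members past the test. All 9 amnion and chorion epithelial markers had a lower mean, with the basal keratin genes KRT14 at 0.447 ± 0.119 against 13.4 ± 19.7 and KRT5 at 0.065 ± 0.047 against 5.77 ± 8.0 (camera adjusted p = 0.00269, and adjusted p = 0.813 with an estimated correlation). KRT14 was 47.5 RPKM in Normal 5 and 0.00 in Normal 3, a wider range than the difference between the group means. Of the 23 extravillous trophoblast markers, 11 had a higher and 12 a lower mean (camera adjusted p = 0.963), and HLA-G was 42.6 ± 31.6 against 73.8 ± 85.8 RPKM, with a log2 difference of 0.04. For this list the mean (-0.10) and the median (-0.02) of the log2 differences were below 0 while the test direction was up. The cytotrophoblast call was lost without Normal 1, PTB 1 or PTB 3 (camera adjusted p = 0.054, 0.101 and 0.0747), with mean log2 differences of -0.40, -0.45 and -0.44 against -0.48 with all libraries. It was kept without Normal 3 (-0.82) and without both Normal 2 and Normal 4 (-0.21). The amnion call was lost with voom and with a mean RPKM of at least 2 (camera adjusted p = 0.0812 and 0.0573), where the mean log2 differences were -1.29 and -1.18 against -1.06. It was kept without Normal 5 and with no filter on low values, each with a mean of -0.65.

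Lymphocyte and antigen presentation lists had higher mean scores in PTB. With an estimated correlation these calls were lost (adjusted p = 0.813 for each list). The exact permutation p of the score difference was 0.1964 for MHC class II and 0.4107 for the interferon response. All 13 measured T, B and NK cell markers had a higher mean in PTB, and the list was called higher (camera adjusted p = 3.99e-07, and adjusted p = 0.813 with an estimated correlation). Its score was 0.31 ± 0.12 in PTB and -0.19 ± 0.28 in Normal samples, with an exact permutation p = 0.07143. When adjusted over the list alone, 2 members passed, GZMB and CD2, and over all genes 0 passed. The filter asks for 0.5 RPKM in 3 samples, the size of the PTB group, so markers high in PTB pass more readily. CD2 passed it through the PTB libraries and Normal 1, with at most 0.166 RPKM in the other Normal libraries. The filter may have favoured both the 13 of 13 higher means and the 2 members that passed. All 10 measured genes of MHC class II presentation had a higher mean (camera adjusted p = 6.86e-07, and adjusted p = 0.813 with an estimated correlation). HLA-DRA was 33.5 ± 31.2 against 13.7 ± 14.8 RPKM and HLA-DPB1 was 29.8 ± 29.2 against 11.02 ± 10.94, with Normal 1 at 40.0 RPKM of HLA-DRA, above 2 of the 3 PTB libraries. Of the 20 interferon response genes, 17 had a higher mean, with GBP2 at 16.0 ± 6.3 against 12.2 ± 4.6 and IFI44 at 9.42 ± 2.79 against 7.24 ± 2.27 (camera adjusted p = 0.0108, and adjusted p = 0.813 with an estimated correlation). The interferon call was lost without Normal 3, Normal 4, Normal 5 or PTB 3 (camera adjusted p = 0.0538, 0.0981, 0.0531 and 0.0657), with mean log2 differences of 0.13, 0.11, 0.15 and 0.11 against 0.17 with all libraries. It was also lost without both Normal 2 and Normal 4 (0.08, adjusted p = 0.404), and kept without Normal 1 (0.31) and with the total without globin and mitochondrial reads (0.28). The MHC class II call was kept without PTB 2, with a mean of 0.38 against 0.89. The T, B and NK cell call was kept with no filter, with each other scaling and with each library left out, and was not tested with a mean RPKM of at least 2, which left too few members. Its mean of 0.50 became 1.07 with a pseudocount of 0.1, 1.33 with voom and 0.33 with no filter.

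Endothelial, stromal and decidual lists had higher mean scores in PTB, with mean log2 differences of 0.38, 0.26 and 0.73 (exact permutation p = 0.25, 0.4643 and 0.375). With an estimated correlation these calls were lost (adjusted p = 0.813 for each list). Of 19 endothelial markers, 18 had a higher mean, with PECAM1 at 190 ± 1.6 against 139 ± 49 RPKM and PLVAP at 127 ± 25 against 77.2 ± 30.6, and ECSCR at 76.1 ± 10.1 against 55.7 ± 29.04 (camera adjusted p = 2.86e-05, and adjusted p = 0.813 with an estimated correlation). PECAM1 was 52.2 RPKM in Normal 4, the library with the highest CSH1, and 153 to 164 in the other Normal libraries. Of 22 villous fibroblast and matrix genes, 18 had a higher mean (camera adjusted p = 0.00919, and adjusted p = 0.813 with an estimated correlation). POSTN was 38.7 ± 27.8 against 17.1 ± 3.6, FBLN1 was 20.9 ± 1.1 against 82.6 ± 101.9, and COL1A1 was 132 ± 4.0 against 154 ± 107. COL1A1 was 344 RPKM in Normal 5 and 96.2 to 116 in the other Normal libraries, and its log2 difference was 0.32 without Normal 5. FBLN1 was 257 RPKM in Normal 4 and at most 89.9 in the other Normal libraries. Of 13 markers chosen for the stroma and glands of the decidua, the maternal lining, 11 had a higher mean (camera adjusted p = 0.00821, and adjusted p = 0.813 with an estimated correlation). Whether all of their reads come from maternal tissue was not tested. PAEP was 110 ± 170 against 3.47 ± 7.12, IGFBP1 was 219 ± 214 against 80.8 ± 132.1, and PRL was 4.38 ± 3.98 against 1.33 ± 1.41. IGFBP1 ranged from 0.842 to 429 RPKM within PTB and from 0.420 to 314 within Normal samples. The decidual call was lost without PTB 3, Normal 3 or Normal 5 and with no filter on low values (camera adjusted p = 0.243, 0.0764, 0.0531 and 0.0579), with mean log2 differences of 0.19, 0.47, 0.56 and 0.59 against 0.73. It was kept without PTB 2 (1.47), without both Normal 2 and Normal 4 (1.32), with voom (1.19) and with array weights (1.14). The fibroblast call was lost without Normal 1, Normal 3, Normal 4, PTB 1 or PTB 3 (camera adjusted p = 0.078, 0.0538, 0.0982, 0.0674 and 0.243), with mean log2 differences of 0.21, 0.20, 0.16, 0.15 and 0.076 against 0.26. It was also lost without both Normal 2 and Normal 4 (0.14, adjusted p = 0.355), and kept without Normal 5 (0.45) and without PTB 2 (0.55). The endothelial call was kept without Normal 4 (0.16), without both Normal 2 and Normal 4 (0.17) and with array weights (0.25), against 0.38.

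**Figure D3:**
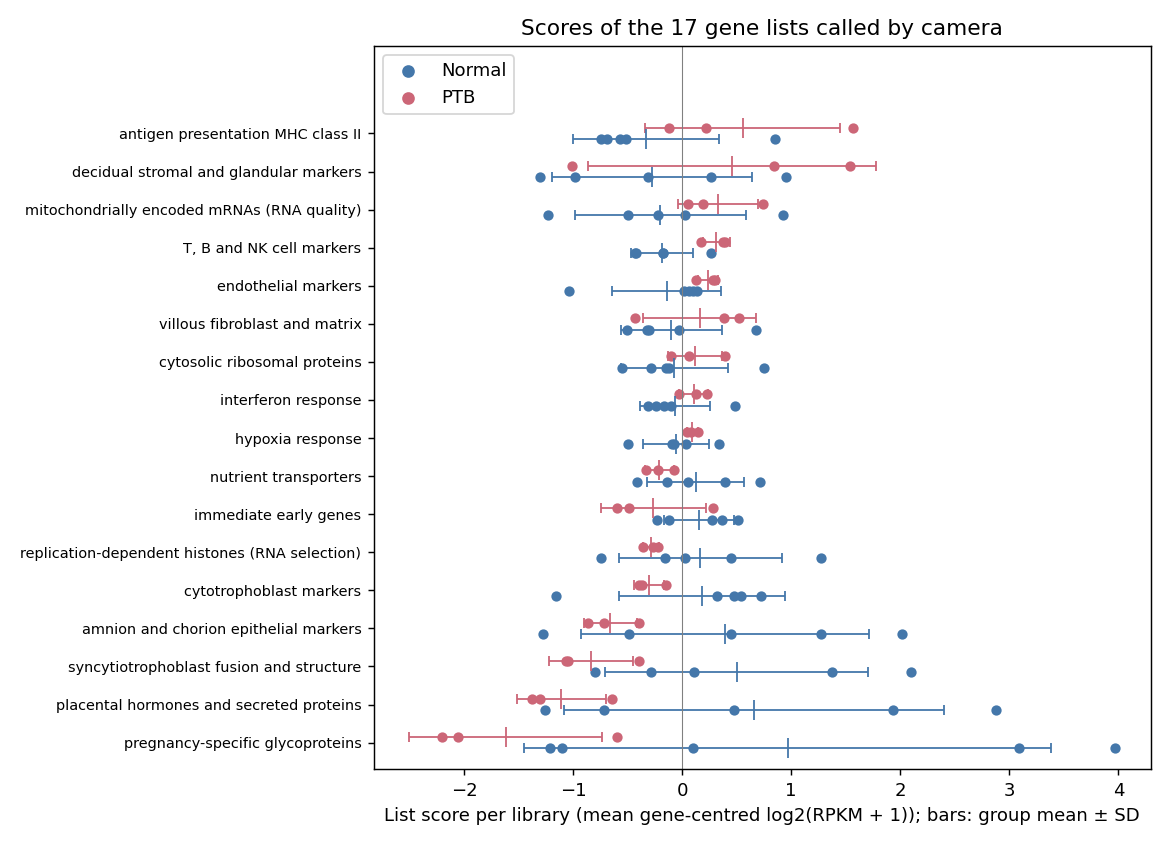
Each row is 1 of the 17 gene lists called by camera with its preset correlation, and each point is the score of 1 library (mean over members of gene-centred log2(RPKM + 1), blue for 5 Normal and red for 3 PTB), with bars for the group mean ± SD. The pregnancy-specific glycoprotein score averaged -1.62 in PTB and 0.97 in Normal samples, and in 0 of the 17 lists did the groups separate fully.

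The lists of the immediate early response and of nutrient uptake had lower mean scores in PTB, and the hypoxia list had a higher one. With an estimated correlation these calls were lost (adjusted p = 0.813 for each list). The exact permutation p of the score differences was 0.1786, 0.2857 and 0.5179. The PTB hypoxia scores, 0.049 to 0.15, lay within the Normal range of -0.49 to 0.34. Of 23 immediate early genes, 18 had a lower mean, with EGR1 at 43.0 ± 45.4 against 95.1 ± 31.4 RPKM and FOS at 58.9 ± 40.9 against 130 ± 49 (camera adjusted p = 0.00919, and adjusted p = 0.813 with an estimated correlation). Of 26 nutrient transporters, 19 had a lower mean, with the amino acid transporter genes SLC7A5 at 0.296 ± 0.208 against 3.54 ± 4.797 and SLC43A2 at 1.83 ± 0.42 against 9.29 ± 10.81 (camera adjusted p = 0.0385, and adjusted p = 0.813 with an estimated correlation). Of 21 hypoxia response genes, 14 had a higher mean, with DDIT4 at 20.3 ± 7.5 against 9.23 ± 3.67 and the glucose transporter gene SLC2A3 at 5.79 ± 2.19 against 3.21 ± 0.62 (camera adjusted p = 0.0299, and adjusted p = 0.813 with an estimated correlation). The hypoxia call was lost without Normal 3, Normal 2, Normal 5 or PTB 2 (camera adjusted p = 0.32, 0.0532, 0.064 and 0.16), with mean log2 differences of 0.039, 0.14, 0.14 and 0.15 against 0.15. It was kept without Normal 4 (0.25), without both Normal 2 and Normal 4 (0.27), with quantile normalisation (0.23) and with the total without globin and mitochondrial reads (0.26). The immediate early call was lost without PTB 1, PTB 3 or Normal 3 (camera adjusted p = 0.41, 0.235 and 0.082), with mean log2 differences of -0.26, -0.31 and -0.49 against -0.42. It was kept without PTB 2 (-0.70), without both Normal 2 and Normal 4 (-0.24) and with array weights (-0.65). The nutrient transporter call was lost without Normal 1, Normal 4, PTB 1 or PTB 3 (camera adjusted p = 0.0633, 0.127, 0.0842 and 0.423), with mean log2 differences of -0.35, -0.18, -0.40 and -0.27 against -0.33. It was also lost without both Normal 2 and Normal 4 (-0.04, adjusted p = 0.348) and with a mean RPKM of at least 2 (-0.37, adjusted p = 0.117), and kept with voom (-0.56) and a pseudocount of 0.1 (-0.51).

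Mitochondrially encoded and ribosomal protein lists had higher mean scores in PTB and the histone list a lower one (exact permutation p = 0.3214, 0.5536 and 0.3929). With an estimated correlation these calls were lost (adjusted p = 0.813, 0.897 and 0.813). The share of mitochondrial reads was 27.4% ± 7.2 in PTB and 20.6% ± 11.3 in Normal samples. All 13 mitochondrially encoded mRNAs had a higher mean in PTB, with MT-ND2 at 32154 ± 10529 against 20615 ± 10438 RPKM and MT-ND4L at 29988 ± 6702 against 20982 ± 12442 (camera adjusted p = 0.000174, and adjusted p = 0.813 with an estimated correlation). Of 39 cytosolic ribosomal protein genes, 35 had a higher mean, with RPL35 at 116 ± 25 against 90.3 ± 47.5 and RPS18 at 70.7 ± 20.8 against 54.3 ± 28.96 (camera adjusted p = 0.000484, and adjusted p = 0.897 with an estimated correlation). All 9 replication-dependent histone genes had a lower mean, with HIST1H1C at 44.7 ± 4.6 against 138 ± 148 and HIST1H2BC at 1.44 ± 0.52 against 4.34 ± 4.28 (camera adjusted p = 0.0364, and adjusted p = 0.813 with an estimated correlation). Without both Normal 2 and Normal 4, 0 of these 3 lists were called (camera adjusted p = 0.456, 0.326 and 0.972), with mean log2 differences of 0.085, -0.040 and 0.010 against 0.53, 0.19 and -0.45 with all libraries. The mitochondrial call was also lost without PTB 2 and with quantile normalisation (camera adjusted p = 0.155 and 0.197), with means of 0.32 and 0.094, and kept without Normal 4 (0.27) and without Normal 3 (0.81). The ribosomal call was also lost without Normal 4 or PTB 3 (camera adjusted p = 0.131 and 0.181), with means of 0.073 and 0.057, and kept without Normal 1 (0.40), without PTB 2 (0.30) and with the total without globin and mitochondrial reads (0.31). The histone call was also lost without Normal 1, Normal 3, Normal 4, PTB 1 or PTB 3 (camera adjusted p = 0.0511, 0.194, 0.262, 0.101 and 0.0875), with means of -0.49, -0.53, -0.18, -0.48 and -0.46. It was lost as well with array weights, voom, no filter and a mean RPKM of at least 2 (camera adjusted p = 0.382, 0.0511, 0.0906 and 0.06), with means of -0.29, -0.56, -0.25 and -0.57, and kept without Normal 5 (-0.68).

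The other 19 lists were not called, with the lowest camera adjusted p at 0.0877. They include inflammatory cytokines, prostaglandin and labour-associated genes, Hofbauer cells and macrophages, neutrophils, angiogenic factors, matrix metalloproteinases, erythroid genes, steroid synthesis, the cell cycle and imprinted genes. Their scores differed between groups by -0.50 to 0.13, and in 10 of them the mean, the median and the test direction were not all of the same sign. IL1B was 1.45 ± 0.070 RPKM in PTB and 0.80 ± 0.51 in Normal samples, CXCL8 was 0.629 ± 0.264 against 0.615 ± 0.390, and S100A8 was 1.77 ± 0.81 against 1.85 ± 1.34, with a log2 difference of 0.07. PTGS2, the inducible prostaglandin synthase gene, was 0.344 ± 0.165 against 1.10 ± 0.64. CD163, a macrophage marker, was 19.5 ± 9.3 against 31.3 ± 18.4, and FLT1, which encodes a receptor of vascular endothelial growth factor, was 73.1 ± 17.8 against 97.5 ± 67.5. HBB was 40.3 ± 16.5 against 60.9 ± 34.5 and the fetal globin gene HBG2 was 121 ± 62 against 73.1 ± 15.8. Each of these genes had a limma adjusted p between 0.880 and 0.975. When adjusted over the list alone, 1 of the 14 matrix metalloproteinase genes passed, MMP1, and 0 passed over all genes.

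In the test of list scores, 0 of 36 lists differed between groups, with a lowest adjusted exact permutation p of 0.8665 and 0 lists with an unadjusted exact p below 0.05. The design allows an exact p of 0.0179 at the smallest.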

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

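The tests of decidua as a source of PRAME, of the trophoblast share and of the number of genes in other splits were chosen after the results were seen. In the group of 5 Normal libraries, 115 measures (named genes, list scores, read shares and the first principal component) were screened for a library far from the others. A measure is listed where the gap between the extreme library and its nearest neighbour, divided by the range, exceeded 0.71. Chance passes about 5% of groups, or 5.75 of 115, and 17 measures passed, many of them related to each other. The 3 PTB libraries were too few to screen.

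Normal 1 was the highest Normal library in GZMB, CD2, HLA-DRA and HLA-DPB1, while GNLY, another T, B and NK cell marker, was higher in Normal 2. The ratio was 0.739 for GZMB (1.64 RPKM, others at most 0.526), 0.737 for CD2 (0.789 RPKM, others at most 0.166), 0.799 for HLA-DRA (40.0 RPKM, others at most 9.04) and 0.803 for HLA-DPB1 (30.5 RPKM, others at most 7.19). It was 0.856 for the MHC class II score, 0.744 for the interferon response score and 0.873 for the oxidative phosphorylation score. Normal 4 was lowest in PECAM1 (ratio 0.937, 52.2 RPKM) and in the endothelial score (ratio 0.903) and highest in LEP (ratio 0.841, 56.2 RPKM against at most 2.62). Normal 3 was lowest in the cytotrophoblast score (ratio 0.783), the Hofbauer cell and macrophage score (ratio 0.790), the senescence and apoptosis score (ratio 0.720) and the number of genes with reads (ratio 0.818, 26899 genes against at least 28238), and it had the highest mitochondrial share of the group at 39.07%. Normal 5 was highest in COL1A1 (ratio 0.851, 344 RPKM against at most 116). Normal 2 was highest in PAEP (ratio 0.797, 16.2 RPKM against at most 0.826) and in the share of globin reads (ratio 0.796, 0.111% against at most 0.072%).

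The counts of genes and lists were set against all 56 splits of the 8 libraries into 5 and 3. For genes higher and for genes lower in PTB, 56 of 56 splits gave as many, since the real counts were 0, and the highest other counts were 2 and 0. For gene lists, 6 of 56 splits called at least the 17 lists of the real grouping, with up to 19 in another split. Every split called lists, with 6 as the lowest number, so camera at its preset correlation calls lists under any grouping. Chance cannot be excluded for the number of lists called. The estimated correlation of the 17 called lists ran from 0.24 to 0.99, above the preset 0.01. An unadjusted p below 0.05 was reached by 603 genes in the real split and by up to 4632 genes in another, where chance gives 859. In 23 of the 56 splits at least 603 genes did, the real one included.

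Syncytiotrophoblast transcripts were lower in PTB, with a difference of -1.90 in the mean score of the 3 lists. In 9 of the 56 splits the difference was as large in size, with 2.85 as the largest of the others, so chance cannot be excluded. Mitochondrial and globin reads in the RPKM denominator are argued against, since 98.6% of the difference was left after rescaling without them. A smaller share of trophoblast cells of every type remains open. The mean cytotrophoblast and extravillous score differed by -0.29 (exact permutation p = 0.607), against -1.90 for the syncytiotrophoblast score. The syncytiotrophoblast score minus that mean differed by -1.61, with an exact permutation p = 0.1429, which does not decide the question with these few samples. The pregnancy group, gestational length and where on the placenta the piece was taken may all contribute, and cannot be told apart here. Gestational length and site are not given in the sources used here.

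PRAME was higher in every PTB library. In 11 of the 56 splits the lowest adjusted p of any gene was as low as the 0.0847 seen here, down to 0.00569, so chance cannot be excluded. To test maternal decidua in the PTB pieces, Normal libraries were set against the lowest PTB decidual score, -1.01 in PTB 2. Above it were 4 Normal libraries, with at most 0.110 RPKM of PRAME, against at least 0.836 RPKM in PTB. That bar was low (Normal 5 passed it at -0.98) and PRAME was already known to be near 0 in Normal, so this count cannot decide. PRAME did not follow the decidual score in Normal 4 (score 0.95, PRAME 0.00 RPKM) or PTB 2 (0.836 RPKM). Those libraries argue against decidua as its only source. Reads shared with PRAME paralogs cannot be told apart, because only 4 of 24 family genes have a row in the table. Those rows held at most 1 read in a PTB library. A link to the pregnancy group may exist and stays untested beyond these samples.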

How the results depend on the processing

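The tests with voom, with the syncytiotrophoblast score as a covariate and without Normal 2 and Normal 4 were chosen after the results were seen. The number of genes higher in PTB was 0 in 17 of 22 alternatives and 1 (PRAME) with median-of-ratios scaling, quantile normalisation, the total without globin and mitochondrial reads, array weights and at an adjusted p below 0.1. It was 0 for genes lower in PTB in all 22, and 0 list score differences held in all 10 alternatives. Gene lists called were 17, and between 14 and 18 with the other scalings, filters, weightings, voom and the block, 12 with the syncytiotrophoblast score as a covariate, 11 without Normal 2 and Normal 4, and 0 with an estimated correlation and with fry. With 1 library left out they ranged from 10 (without PTB 3) to 17. The first principal component difference, -0.97 in SD units, kept its direction from -1.31 to -0.23. Of 73 named genes, 53 kept their direction in every alternative in which they were tested and 72 passed the test in none. Of the 73, 56 were tested with a mean RPKM of at least 2, and the total without globin and mitochondrial reads leaves out globin and mitochondrial genes. Of the 17 called lists, 11 kept the direction of the camera test, which compares a list with other genes, in every alternative in which they were tested, and the mean log2 difference kept its sign in all of those for 11, which are not all the same lists. At these sample numbers, the test recovered 36 of 100 genes changed 4-fold in simulated reads with the spread of these libraries and 98 of 100 with a dispersion of 0.05, so the spread between libraries limits the calls.

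The labels do not say that the replicate numbers pair the samples, and the values showed no pairing. The deviations of same-numbered samples correlated at -0.25, -0.20 and 0.05, and Normal 1, 2 and 3 correlated best with PTB 2, 1 and 2. These correlations over all genes cannot exclude a pairing. With the replicate block, 0 genes were higher, 0 were lower and 14 lists were called, of which 13 were among the 17. The calls lost were those of amnion and chorion epithelium (mean log2 difference -0.22 against -1.06, camera adjusted p = 0.0683), the interferon response (0.060 against 0.17, 0.44), ribosomal proteins (0.0080 against 0.19, 0.823) and mitochondrial mRNAs (0.18 against 0.53, 0.112). FLT1 was 0.26, COL1A1 0.28 and S100A8 -0.10 in log2 difference, the reverse of their values without the block (-0.12, -0.02 and 0.07).

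The other genes that reversed passed no test in any alternative, while the lists that reversed had been called. The cause was not tested. In log2 difference, FLT1 was 0.00687 and COL1A1 0.10 with the total without globin and mitochondrial reads, COL1A1 was 0.0296 with median-of-ratios scaling and 0.0614 with quantile normalisation, and CXCL8 was -0.0331 with array weights. With 1 library left out, FLT1 ranged from -0.52 to 0.20, HLA-G from -0.82 to 0.70, CXCL8 from -0.0747 to 0.16, S100A8 from -0.19 to 0.35 and COL1A1 from -0.13 to 0.32. With the syncytiotrophoblast score as a covariate, chosen after seeing the data, log2 differences were 0.0425 for CSH1, 0.17 for CYP19A1, 0.11 for KISS1, 0.54 for FLT1, 0.0330 for HBB, 0.39 for CD163, 0.75 for PAPPA2, 0.00529 for TREML2, 0.58 for EGFR, 0.63 for FBLN1, -0.16 for ECSCR, 0.0865 for SLC43A2, 0.11 for SLC7A5, -0.13 for MT-ND4L, 0.45 for HIST1H1C and 0.34 for HIST1H2BC. The mean became 0.0583 for placental hormones and 0.0276 for cytotrophoblast markers, with the camera direction still lower. Against other genes, 6 lists reversed in the camera direction, with means of 0.0757 for villous fibroblasts, 0.0441 for endothelium, 0.13 for nutrient transporters, -0.0462 for ribosomal proteins, -0.20 for mitochondrial mRNAs and 0.25 for histones, and the ribosomal and mitochondrial lists were called lower (camera adjusted p = 0.0327 and 0.00378). Without Normal 2 and Normal 4, also chosen after seeing the data, FLT1 was 0.17, FBLN1 0.0371, ribosomal proteins -0.0395 and histones 0.0102. The count-model alternatives planned for a table of raw counts were not run.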

Other observations

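The tests in this part, and the genes named in it, were chosen after the results were seen. Transcripts typical of hepatocytes were present at low levels and differed between libraries. ALB, the serum albumin gene, was 3.67 ± 0.59 RPKM in PTB (SD, n = 3) and ranged from 0.672 to 4.85 RPKM in Normal libraries. FGB, which encodes the fibrinogen beta chain, was 3.31 ± 2.39 against 0.758 ± 0.755 RPKM, and FGA was 1.17 ± 0.61 against 0.270 ± 0.259 RPKM. APOA2 was 1.42 ± 0.56 against 0.454 ± 0.462 RPKM. AFP, the fetal liver and yolk sac gene, was at most 0.036 RPKM in any library. SERPINA1, which macrophages also express, was 23.3 RPKM in PTB 2, 4.85 in PTB 1 and 3.34 in PTB 3, and ranged from 1.52 to 7.31 RPKM in Normal libraries.

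Of 29 hepatocyte genes, 14 passed the filter on low values and 0 were tested members of the lists fixed in advance. The filter asks for 0.5 RPKM in 3 samples, the size of the PTB group, so genes high in PTB pass more readily. FGA passed through the PTB libraries and Normal 2, with at most 0.412 RPKM in the other Normal libraries. The score of the 14 genes was higher in PTB by 0.63, with an exact permutation p = 0.03571, in 3 of 3 PTB libraries above every Normal library. The filter may have favoured that difference. The 4 genes that prompted the list were ALB, APOA2, ORM2 and FGB. Without them the score of the other 10 differed by 0.54, with an exact permutation p = 0.03571. Those 10 are transcripts of the same kind in the same libraries, so this is not independent support. The difference is a hypothesis found and tested on the same libraries, with no correction for the lists looked at, and it may be linked to the pregnancy group. A shared source of liver RNA with a fixed composition is argued against by the ratio of FGB to ALB reads. It differed by 12.2 times, from 0.0952 in Normal 1 to 1.16 in PTB 1. The 95% lower bound of 6.67 covers counting error only if each read is independent, which was not tested. It does not cover the choice of the extremes. The reads were 12 of FGB and 126 of ALB in Normal 1, 694 and 598 in PTB 1, and 195 and 707 in Normal 2. Maternal blood plasma, local expression and sample handling were not tested.

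Decidual transcripts varied within both groups. IGFBP1 was 429 RPKM in PTB 3 and 227 RPKM in PTB 1 but 0.842 RPKM in PTB 2, and it was 314 RPKM in Normal 4 but 0.420 RPKM in Normal 5. PAEP, a glandular secretory gene, was 306 RPKM in PTB 3 and 22.9 RPKM in PTB 1, and 16.2 RPKM in Normal 2. KRT14 and KRT5 were 47.5 and 18.5 RPKM in Normal 5, and KRT17 was 60.4 RPKM in that library.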
